A study of Mus musculus with 6 samples.

How the data were processed

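ATAC-seq libraries came from sorted mKate2-positive, CD45-negative, DAPI-negative pancreatic epithelial cells of male KC mice, with 3 libraries from rIL-33 treatment and 3 from PBS. The deposited signal was 1 table of normalized counts, with 1 column per library and 1 common set of 77391 regions from 200 to 17434 bp wide. Per the submitters' processing notes, the tools were Trim Galore, Bowtie2 2.2.2, featureCounts 1.6.0, DESeq2 and bedtools, and the genome build was mm9. The notes used here give these names without their role or order. The peak caller, the merging of peaks, the treatment of duplicate reads and any shift of read ends for the transposase were not given in the sources used here. Each of these could change the counts of single regions: duplicates left in make counts less independent than separate molecules, and the choice of peak caller and merging sets region borders and widths.

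Each deposited column was made of whole multiples of a single step. Dividing by that step gave whole reads for 100% of the values (within 0.001 of a whole number). Median-of-ratios size factors computed from the recovered reads matched the deposited scaling, with a largest relative difference of 8.9e-16. Whether featureCounts counted reads or read pairs was not given in the sources used here, so the word reads stands for either. Total recovered reads ran from 3616672 in rIL-33 replicate 1 to 8716549 in rIL-33 replicate 2. Replicates were taken from the labels. A check for repeated deposits of a library found no pair that agreed within counting noise (chi-square per degree of freedom between 1.41 and 5.92 over the 15 pairs), which does not show that the libraries came from separate mice. Start positions are given counting from 1, where the deposited table counts from 0.

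The main test, chosen before the data were examined, was limma-trend with robust empirical Bayes (limma 3.58.1, R 4.3.3) on log2(normalized count + 1). It was run on regions with a mean of at least 10 over the 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 and no covariate. Fold changes are on this log2(value + 1) scale, which understates the change of low regions. Rose and fell refer to regions past that threshold. The labels used here do not say outright that each library came from its own mouse, so the p-values measure the spread between these libraries, part of which may be technical.

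Tests with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads were alternatives, as were other pseudocounts, filters, normalizations, spread models and thresholds, the replicate number as a block, and leaving out each library. Two-group exact permutation tests were used for single values per library. The fitting code was tested on simulated counts drawn from the real means and library sizes, of which 68714 regions passed the filter for limma-trend. With 40 regions planted at each size, limma-trend recovered 0% of 1.5-fold gains, 17.5% of 2-fold gains and 75% of 4-fold gains, 22.5% of losses to 0.5 and 70% of losses to 0.25, with 2 false calls. Gains under 2-fold were thus mostly not detectable at this depth, spread and number of libraries. The simulated libraries held no differences shared across regions, so the 2 false calls may understate those in the real libraries. There a split that mixed the treatments gave 38 calls.

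Regions were named by a rule fixed before the data were examined. It took the 12 largest gains and up to 12 largest losses among called regions whose rIL-33 values all lay on one side of the PBS values and whose mean was above the median tested region. Only 2 regions met it for losses. Regions in neighbouring groups were joined when less than 100 kb apart. Random sets for neighbours and widths were drawn within 20 classes of mean signal.

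The last region of every chromosome ended within the mm9 chromosome lengths (GenomeInfoDb 1.38.1). The gene table at hand was of another mouse build, and no mm9 annotation or genome was used here. Regions therefore carry no gene names, and the planned tests of gene lists, promoter share and sequence motifs, and the named regions tied to genes, were not run. What genes, exons, introns or UTRs the regions overlap was not analysed here.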

Results

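Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in pancreatic epithelial cells of KC mice. In these mice a Cre recombinase active in the pancreas switches on the mutant allele KrasG12D together with the red fluorescent protein mKate2. Cells positive for mKate2 and negative for the immune marker CD45 and for the dead-cell dye DAPI were sorted. Male mice received either murine recombinant IL-33 (rIL-33), a cytokine released by damaged tissue, at 1 ug per day by intraperitoneal injection for 5 days, or the vehicle PBS. Pancreata were taken on the last treatment day, which the labels call day 0. There were 3 libraries per group. The labelled age was 5 weeks for each library except PBS replicate 3, for which it was 6 weeks.

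The deposited table held 77391 regions of the mm9 mouse genome. The reads in these regions numbered 5003875, 7018100 and 6793564 in PBS replicates 1, 2 and 3, and 3616672, 8716549 and 7029415 in rIL-33 replicates 1, 2 and 3. The median region held between 15 reads, in rIL-33 replicate 1, and 44 reads, in rIL-33 replicate 2. Counting error alone gave a relative SD of 25.8% and 15.1% at those medians. The mitochondrial genome, entered as 1 region, took 13.9% ± 1.44 of the reads in PBS libraries and 14.9% ± 4.30 in rIL-33 libraries (SD, n = 3 each). This difference was smaller than the spread between libraries (exact permutation test, two-sided p = 0.9, where the smallest p that 3 against 3 libraries allow is 0.1). In rIL-33 replicate 1, the shallowest library, the share was 19.8% (95% exact binomial interval 19.7% to 19.8%, counting error only).

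The comparison of rIL-33 with PBS asks how the cytokine altered accessible chromatin in Kras-mutant pancreatic epithelium. Almost all of the detected change was gain of accessibility. Each library measured many sorted cells together, so a gain within cells cannot be told apart from a change in the mix of cells. Of 70037 regions tested, 363 rose and 2 fell after rIL-33 (limma-trend, Benjamini-Hochberg adjusted p under 0.05). The risen regions gained a median of 1.38 on the log2 scale, or 2.59-fold, with a range of 0.70 to 3.78. Of them, 307 gained at least 2-fold and 49 at least 4-fold. At an unadjusted p under 0.05, 4411 regions were higher and 1280 lower in rIL-33, where chance would give 1751 each way.

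The largest gain among the regions named by the preset rule lay on chromosome 5 (40197857 to 40198462). It went from 4.03 ± 1.36 normalized counts in PBS to 69.9 ± 25.7 in rIL-33 (SD, n = 3 each), a log2 fold change of 3.78 ± 0.39 (SE, adjusted p = 1.12e-05, limma). In recovered reads it held 2, 6 and 5 in PBS replicates 1, 2 and 3, against 50, 64 and 91 in rIL-33 replicates 1, 2 and 3. A region of 1970 bp on chromosome 3 (106001877 to 106003846) went from 27.2 ± 13.7 to 221 ± 50.2 normalized counts (SD, n = 3 each), a log2 fold change of 3.10 ± 0.30 (SE, adjusted p = 1.12e-05, limma). On the same chromosome, the region from 106022301 to 106023614 went from 11.1 ± 1.38 to 88.3 ± 39.8 normalized counts, a log2 fold change of 2.80 ± 0.32. A region on chromosome 19 (28403001 to 28403757) went from 14.5 ± 6.15 to 115 ± 37.3, a log2 fold change of 2.92 ± 0.32. A region on chromosome 8 (47760153 to 47760860) went from 8.96 ± 4.23 to 68.9 ± 22.3, a log2 fold change of 2.84 ± 0.36.

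The other 7 named regions that rose gained between 5.01-fold and 6.56-fold. They began at 87.15 Mb on chromosome 16, 28.58 Mb on chromosome 11, 129.11 Mb on chromosome 6, 157.82 Mb on chromosome 3, 137.08 Mb on chromosome 1, 42.59 Mb on chromosome 6 and 166.34 Mb on chromosome 1. Their PBS means ranged from 9.19 to 20.4 normalized counts and their rIL-33 means from 60 to 89.8. The last of them had the widest PBS spread, 20.4 ± 17.4 (SD, n = 3), because PBS replicate 2 stood at 40.4 against 11.1 and 9.58 in PBS replicates 1 and 3. Its call was lost without PBS replicate 3, without rIL-33 replicate 1, without rIL-33 replicate 3 and under DESeq2, with log2 fold changes of 1.97, 2.19, 2.16 and 2.12 against 2.33 and an adjusted p of up to 0.194 over 21 refits. Without rIL-33 replicate 1, the regions at 87.15 Mb on chromosome 16, at 129.11 Mb on chromosome 6 and at 137.08 Mb on chromosome 1 also lost their calls, with log2 fold changes of 2.58 against 2.71, 2.37 against 2.45 and 2.15 against 2.35. The last of these lost it without rIL-33 replicate 3 as well, at 2.17.

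**Figure D1:**
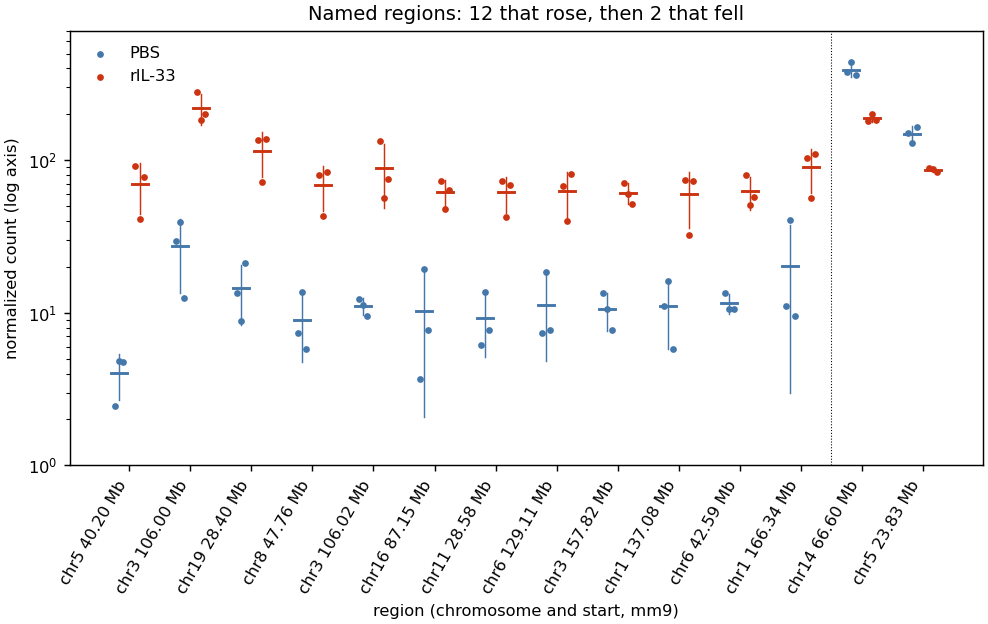
Normalized counts (log axis) of the 12 named regions that rose and, right of the dotted line, the 2 that fell. Points are the 3 libraries of each group, horizontal bars group means and vertical bars 1 SD. In each of the 14 regions the rIL-33 libraries lie apart from the PBS libraries because the naming rule required it.

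Regions with a higher PBS signal also rose. The smallest p belonged to a region on chromosome 10 (94578999 to 94580503), which went from 73.6 ± 6.0 to 308 ± 76.4 normalized counts (SD, n = 3 each), a log2 fold change of 2.02 ± 0.18 (SE, adjusted p = 3.11e-06, limma). A region on chromosome 4 (97132336 to 97133323) went from 105 ± 10.9 to 295 ± 65.6, a log2 fold change of 1.46 ± 0.18. Another on the same chromosome (134862487 to 134863704) went from 54.9 ± 1.37 to 158 ± 21.8, a log2 fold change of 1.5 ± 0.19. These 3 regions lay outside the naming rule. They were chosen after their values were seen, for a high PBS mean among regions of small p. Others of similarly small p had PBS means of 21.1 to 52.7 normalized counts.

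The 2 regions that fell differed in how firmly they were called. A region of 4975 bp on chromosome 14 (66598345 to 66603319) went from 393 ± 43.1 normalized counts in PBS to 188 ± 10.1 in rIL-33 (SD, n = 3 each), a log2 fold change of -1.06 ± 0.15 (SE, adjusted p = 0.000441, limma). It passed the threshold in all 21 refits, with log2 fold changes between -1.12 and -0.97. A region on chromosome 5 (23834997 to 23835965) went from 149 ± 17.8 to 86.8 ± 3.0, a log2 fold change of -0.76 ± 0.18 (SE, adjusted p = 0.0459, limma). Its call was lost in 9 of 21 refits, among them those without PBS replicate 1 or 3 and those without any 1 of the rIL-33 libraries, with an adjusted p of up to 0.351, while its log2 fold change stayed between -0.85 and -0.68.

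**Figure D2:**
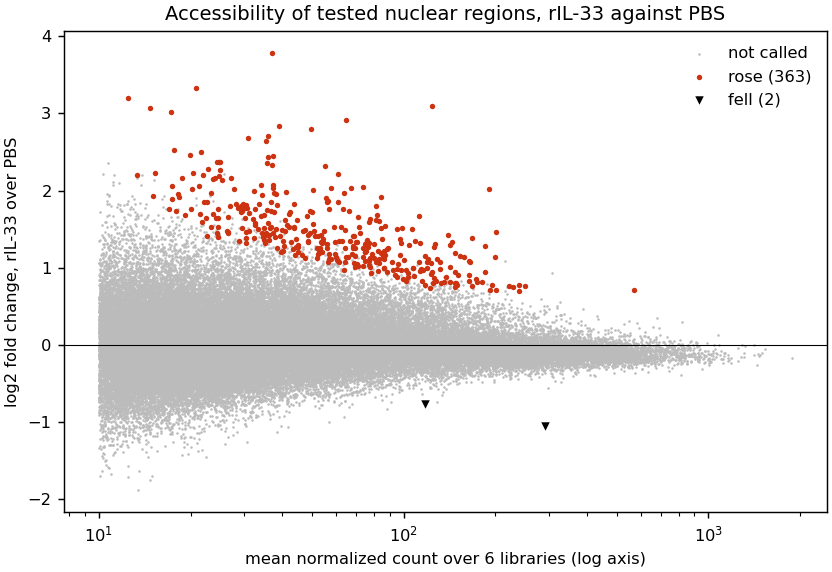
Log2 fold change, rIL-33 over PBS, of each tested nuclear region against its mean normalized count over the 6 libraries (log axis). The 363 regions that rose are red, the 2 that fell are black triangles and regions not called are grey.

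In PBS, the risen regions as a set lay near the median tested region. Their median PBS level was 30.8 normalized counts, against 31.1 over all tested regions, and their median rIL-33 level was 83.0. In PBS, 184 of the 363 (50.7%) lay below the median tested region. In rIL-33, 15 did, a contrast that choosing regions for their gain itself favours. No level for closed chromatin was measured, and regions of low mean signal were filtered out before testing. These levels thus do not show whether the risen regions were open or closed in PBS. The levels are also counts per region, not divided by width. The risen regions were wider, with a median of 694 bp against 460 bp over all tested regions. Random sets of tested regions matched on mean signal had medians of 566 to 622 bp (central 95% of 10000 sets). All 363 had each rIL-33 library above each PBS library. Of all tested regions, 7.47% were separated upward in this way and 5.59% downward, where chance gives 5% each way.

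Some of the risen regions lay side by side. Of the 363, 66 (18.2%) had another risen region within 100 kb, against a mean of 6.10% and a maximum of 12.1% in 1000 random sets matched on mean signal (permutation p = 0.001, one-sided, the smallest these sets can give). Among 18 equally long lists of top regions from other splits of the 6 libraries, the highest share was 15.2% and the next 12.4%. The share was 11.4% without rIL-33 replicate 3 (maximum of 1000 random sets 8.57%). It was 36.4% without PBS replicate 2 (maximum 28.5%), a fit that mixes treatment with a difference between libraries, as given below. With all libraries thinned to equal depth it was 10.7%, a share that 4 of 1000 random sets reached (maximum 11.5%). The 363 formed 328 loci, of which 31 held at least 2 risen regions and 4 held 3. The locus on chromosome 3, from 106001877 to 106030591, held 3 risen regions among 5 tested. The signal summed over all 5 was 87.5 ± 22 normalized counts in PBS and 472 ± 103 in rIL-33 (SD, n = 3 each), a ratio of 5.4. Over all tested regions of the other 3 loci the ratio was 2.38 on chromosome 12 (5 regions, 55560226 to 55590025), 1.56 on chromosome 2 (6 regions, 165965025 to 165983302) and 1.53 on chromosome 9 (11 regions, 34919400 to 34961136). These loci were picked because they held risen regions, so the ratios describe them and are not a separate test. Over a wider reach of 250 kb, 4 risen regions lay among 31 tested on chromosome 10 between 94578999 and 94921669, with log2 fold changes of 2.02, 1.96, 1.67 and 0.80.

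**Figure D3:**
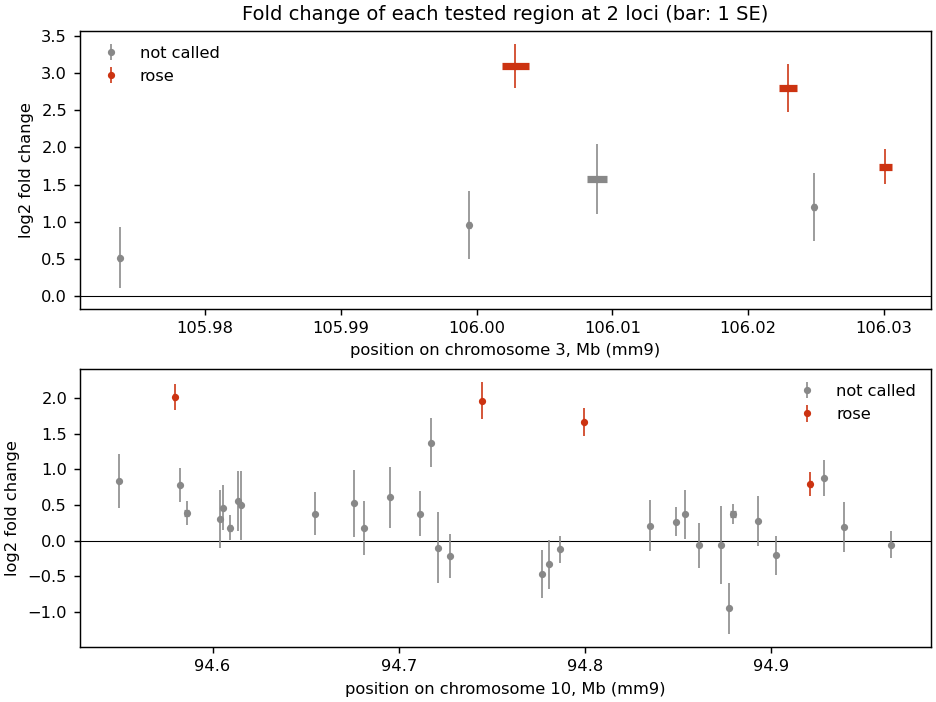
Log2 fold change, rIL-33 over PBS, of each tested region by position (Mb, mm9) at the locus on chromosome 3 that held 3 risen regions and the locus on chromosome 10 that held 4. Thick bars span the regions, thin bars are 1 SE, and risen regions are red.

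The risen regions were spread over the chromosomes. Each of the 19 autosomes and the X chromosome held some. Chromosome 2 had 39 among 5390 tested (Fisher's exact test, two-sided, p = 0.0373), and chromosome X had 3 among 1370 (Fisher's exact test, two-sided, p = 0.177). After adjustment over the 20 chromosomes the lowest adjusted p was 0.477. The mitochondrial region did not pass the threshold, with a log2 fold change of 0.05 ± 0.25 (SE, adjusted p = 0.977, limma).

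The number of called regions depended on single libraries. Without rIL-33 replicate 1, 38 regions were called (37 rose), without rIL-33 replicate 3, 71 (70 rose), and without PBS replicate 1, 121 (120 rose). Without PBS replicate 2, 1875 were called (1675 rose), and without PBS replicate 3, 688 (673 rose). Leaving out PBS replicate 2 kept PBS replicates 1 and 3, at -26.77 and -135.3 on the first principal component. The rIL-33 libraries lay above both, at 5.983 to 52.66. In that fit the effect of rIL-33 cannot be told apart from this difference between libraries. Weighting the libraries by their estimated spread gave 11779 higher and 9300 lower, from a fit of the weights that did not converge. It put a weight of 36.9 on PBS replicate 1, against 0.226 to 1.26 on the other libraries. Weights estimated gene by gene, which also put the most weight on PBS replicate 1, gave 5044 and 1526. PBS replicate 3, the library labelled 6 weeks, had the lowest mean correlation with the other 5 libraries across regions, 0.893 against 0.913 to 0.930.

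**Figure D4:**
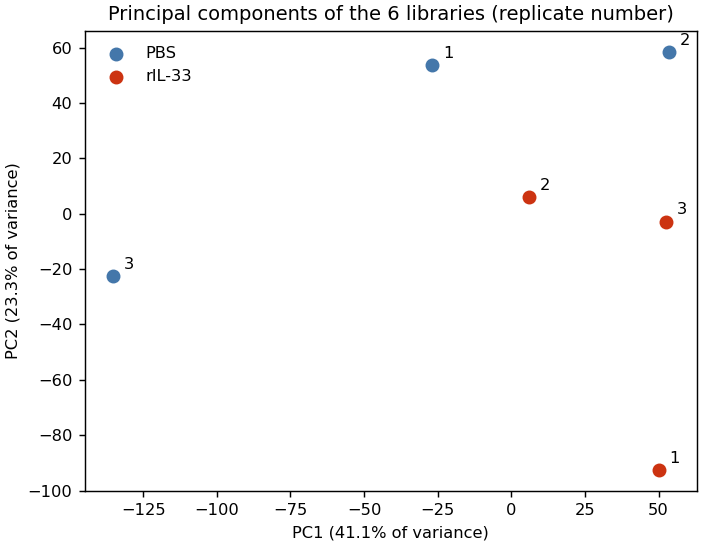
The 6 libraries on the first and second principal components of the log2 normalized counts, which hold 41.1% and 23.3% of the variance. Points are libraries, coloured by group and marked with the replicate number, and PBS replicate 3 lies at -135.3 on the first component.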

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

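Depth thinning, gene-by-gene array weights and the 50 kb and 250 kb neighbour distances were chosen after seeing the data. The tests of neighbours within 100 kb, of widths and of chromosomes were not part of the plan fixed before the data were examined. All 363 risen regions had a positive fold change in every setting in which they were tested, and of 285 refits of the 14 named regions all kept their direction and 268 their side of the threshold. The kept direction is weak evidence. All 363 had each rIL-33 library above each PBS library, and the 14 were named for such separation, so leaving out 1 library could not reverse it. The number called moved. Leaving out 1 library gave 38 to 1875 changed regions, 37 to 1675 higher and 1 to 200 lower. The count was 121 without PBS replicate 1, 1875 without PBS replicate 2, 688 without PBS replicate 3, 38 without rIL-33 replicate 1, 259 without rIL-33 replicate 2 and 71 without rIL-33 replicate 3. Array weights gave 21079 changed regions (11779 higher, 9300 lower) with a weight of 36.9 on PBS replicate 1 and a fit that did not converge. The gene-by-gene weights gave 6570 (5044 higher, 1526 lower) with a weight of 3.92 on that library. In both, the risen share of calls was lower, 55.9% and 76.8% against 99.5%, and the cause was not tested. An adjusted p under 0.1 gave 593 (584 higher, 9 lower), by its looser threshold. The regions lower in rIL-33 numbered 1 with no filter on low values, without robust empirical Bayes and with libraries thinned to equal depth, and 4 with a filter at a mean of 50; the cause was not tested. With the replicate number as a block, 147 regions were called (146 higher, 1 lower). The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.10, -0.21 and -0.22, and none correlated best with its own number. Under the other settings, changed regions numbered 253 to 416, with 321 by edgeR (313 of its risen regions shared) and 341 by DESeq2. At the 100 kb distance, the share of risen regions with a risen neighbour lay above all of 1000 random sets in each setting except equal depth, where it was 10.7% and 4 sets reached it (maximum 11.5%). At 50 kb and 250 kb, run with 200 random sets each, the share was 14.9% (maximum 6.89%) and 23.4% (maximum 19%). Its highest value was 80.7% with array weights (maximum 78.4%), and it was 36.4% without PBS replicate 2 (28.5%) and 11.4% without rIL-33 replicate 3 (8.57%), against 18.2%. Gene lists, promoter share and motifs were not run under any setting, since no mm9 annotation or genome was used here. Small changes were mostly missed in simulation: at the depth, spread and number of these libraries, 17.5% of planted 2-fold gains and 0% of 1.5-fold gains were recovered, and the share due to depth alone was not tested.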

Other observations

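The tests of scaling and of PBS replicate 3 as reasons for the one-sided change were chosen after the results they measure were seen; the held-out pairs, the distance classes and the neighbour tests in other splits were chosen after the main result and the clustering were seen.

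Regions that gained accessibility in some libraries also gained it in libraries left out of the choice. For each of the 9 pairs of 1 PBS and 1 rIL-33 library, the 300 top gains and 300 top losses were picked from the remaining libraries and read in the left-out pair. On average 93.6% of the gains (range 81.7% to 98.7%) were also higher in the left-out rIL-33 library, with a mean of the median log2 difference of 1.08. Of the losses, 45.1% were also lower, from 65.3% to 69.0% with PBS replicate 1 left out and from 19.3% to 43.3% with PBS replicate 2 or 3 left out. Each left-out pair was centred on its median, so about 50% of all tested regions lay on either side. Pairs with the same library left out are not independent. With each PBS partner, rIL-33 replicate 2 gave the smallest held-out gain, with median log2 differences of 0.90, 0.53 and 0.98, against 0.97 to 1.44 with the other rIL-33 libraries. Whether this library differs in its response was not tested.

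Tested regions near a risen region, though not called, were shifted the same way. Within 10 kb, 521 such regions had a median log2 fold change of 0.20 and 72.6% were positive, where 200 random anchor sets matched on mean signal gave at most 0.06. From 10 to 50 kb the median of 1512 regions was 0.088 (random maximum 0.011) and from 50 to 100 kb that of 1659 was 0.034 (random maximum -0.001), both above all 200 random sets. From 100 to 500 kb that of 8981 was -0.02, within the random range of -0.04 to -0.017. A shift of this size within 10 kb was not found in the real split alone, since 1 of the 9 splits that mix the treatments, PBS replicates 1 and 3 with rIL-33 replicate 2 against the rest, gave 0.279 and 0.234 in its 2 directions. The 16 lists of the other 8 splits gave 0.02 to 0.162. The split of PBS replicates 1 and 3 with rIL-33 replicate 2 followed the first principal component. Those libraries lay lowest on it, at -26.77, -135.3 and 5.983, and the rest at 50.02 to 53.45.

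Risen regions outnumbered fallen ones by 363 to 2. Unequal scaling of the libraries is argued against as the whole reason, since the risen share of calls was 99.4% after quantile normalization. Unequal depth is argued against likewise, with 99.6% after thinning all libraries to 2901789 nuclear reads, and so is the library of PBS replicate 3, with 97.8% without it. Without PBS replicate 2, treatment was mixed with the first principal component. The share of that fit was 89.3% (1675 higher, 200 lower), the lowest among fits that left out 1 library. It was lower still, at 55.9% and 76.8%, under the array weights that lean on PBS replicate 1. The counts themselves, 365 changed and 363 risen, were reached by 1 and 1 of the 10 splits of the libraries into 3 and 3, the real split. The highest other split gave 38 and 29, and 10 splits are too few for a share under 0.05. In the other splits each group held libraries of both treatments. Any effect of rIL-33 would widen the spread within those groups and lower their calls.

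The clustering of risen regions has no settled explanation. The uneven density of tested regions along the genome is argued against as the whole reason. The 1000 random sets reached at most 12.1% with a neighbour and the risen regions 18.2%. At equal depth, though, 4 of 1000 sets reached the lower share of 10.7%. The sets were matched on mean signal only. A preference of risen regions for dense stretches, or a part played by their greater width, thus stays open. Scaling of whole segments stays open. Inside the 4 loci with 3 risen regions, 14 of the 15 regions not called were positive. Their median log2 fold change was 0.35, against -0.02 over all tested regions. That this was 24.2% of the median of the called ones excludes nothing, because the calls themselves select the larger changes. At the longer loci joined over 250 kb, fewer of the regions not called were positive. These were 18 of 27 on chromosome 10 and 7 of 15 on chromosome 8 (111114702 to 111326753), against 47.2% of all tested regions. The regions not called at the locus on chromosome 8 thus showed no shared gain. A response to rIL-33 shared by regions nearby may account for the shift of 0.2 within 10 kb, but so may library differences that neighbours share whatever the treatment, since both lists of the split of PBS replicates 1 and 3 with rIL-33 replicate 2 shifted at least as much (up to 0.279). Clustering in any grouping of the libraries stays open on 1 list of that same split, the highest of the 18, with a neighbour share of 15.2%. This lay 3.0 percentage points below the real share, with a counting SE of 2.77. That SE treats regions as independent. Neighbours are counted together and both lists came from the same libraries, so it is likely too small. The next list had 12.4%, and only 1 of the 18, the list at 15.2%, exceeded all of its own 1000 random sets.

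PBS replicate 3 stood apart from the other 5 libraries. Depth is argued against, since after thinning its mean correlation stayed 0.0247 below the next lowest. A trend with signal strength is argued against, with a gap of 0.0234 after cyclic loess. It was also the only library labelled 6 weeks, and with 1 such library age cannot be told apart from any other property of it.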
